A study of Mus musculus with 12 samples.

How the data were processed

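RNA from mouse lenses was measured by sequencing in 12 libraries, 3 for each of 4 genotypes. Per the series' design text, each library was a pool of 6 lenses taken from 3 mice, so the 3 libraries of a group came from separate pools of animals. Polyadenylated RNA was prepared with an Illumina TruSeq kit for single-end reads, and libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The protocols name no step that marks strand, so reads from overlapping genes, and from a gene and its antisense partner, cannot be told apart.

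The deposited table holds FPKM (fragments scaled to transcript length and library size), the unit Cuffnorm reports. Its header names no unit; the unit was read from the tools and from the values, which carry 1 decimal and sum to different totals. Trimmomatic, TopHat2 2.0.9, Cufflinks and Cuffnorm are named per the submitters' processing notes, as is the genome build mm10. The notes used here give these tools no role, order or option. Cuffnorm scales libraries against each other, and the scaling chosen is not given in the sources used here. The filter that left the 14852 loci of the table is not given either.

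Loci are assembled regions with Cuffnorm numbers, not annotated genes. One gene can have several loci, and 722 loci carry several symbols; 926 carry none. For 99.9% of the 11460 loci with a single known symbol, the locus overlapped the GENCODE vM21 gene of that symbol, and coordinates printed for a gene are those of GENCODE on mm10. No read counts are given, so the depth of each library is unknown, and no counting interval or floor was computed. The FPKM of a library summed to between 956509 and 1036642.

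Tests were made on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using lmFit, contrasts.fit and eBayes with a trend of the variance on the mean. All 12 libraries entered 1 fit with 4 group means and no covariate, which left 8 residual degrees of freedom. Loci with a mean of at least 1 FPKM over the 12 libraries were kept, which left 14806. A locus was called at a Benjamini-Hochberg adjusted p under 0.05. Every fold change is therefore a difference on the log2(FPKM + 1) scale, which understates the change of loci with low values. The contrasts were each mutant group against LeCre, Fgfr2Pten against each single mutant, and the interaction. The interaction is the Fgfr2Pten change against LeCre minus the sum of both single changes.

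An exact 0 in such a table can be a failed estimate. The 11 loci listed at 0 in some libraries and at 50 FPKM or more in another were therefore left out of the overlaps. They were also left out of the gene lists, except that of sex-linked genes, where a 0 can reflect sex. Values of some of them are given per library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

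The 27 gene lists were fixed before the data were examined, as were the tests, most other settings tried and the rule for named genes. Set tests used camera with a preset correlation of 0.01 between genes, adjusted over the 24 lists with at least 3 tested members within each contrast. They were repeated with an estimated correlation and with fry. With an estimated correlation, none of the 144 set tests passed the threshold, and the lowest adjusted p was 0.102, so the 39 calls made with the preset value depend on it. In none of these 39 did the median or mean of the list differ in sign from the test.

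Named genes followed a fixed rule. Fgfr2 and Pten came first. In each comparison with LeCre, the 10 largest rises and the 10 largest falls were taken, and in the other contrasts the 5 largest. They had to be called, have groups without overlapping values (not asked of the interaction) and a higher group mean of at least 5 FPKM. Clone and model names and microRNA, snoRNA and ribosomal RNA genes were passed over. From each list, up to 4 called members with the lowest adjusted p were eligible, or the 2 most abundant members where fewer than 2 were called. Eligible members whose call ended when 1 library was left out are mostly given as counts.

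The procedure was tested on simulated data made from Fgfr2 against LeCre, in which 50 of 14752 loci were changed at each of 4 known sizes. It recovered 42% of changes of 0.5 on the log2 scale and 100% of those of 1 or more, and 6.56% of its calls were false. The changed loci had a mean of at least 5 FPKM, and the noise was drawn independently for each locus. These rates therefore do not carry over to lower loci or to spread that loci share within pools. Other settings fixed in advance were a TPM scaling, a median-of-ratios scaling, a pseudocount of 0.1, no filter on low values, fits of only the groups compared, a robust variance prior, a replicate block and leaving out each library in turn. Settings chosen after seeing the data left out the loci listed at 0, or the all-or-none loci and loci within 10 Mb of the targeted genes. Others added the level of the Y-linked gene Eif2s3y or the first axis of the within-group deviations as a covariate.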

Results

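The lens transcriptome was compared between mice with conditional alleles of Fgfr2, of Pten or of both and control mice. Every mouse was hemizygous for Le-Cre, a transgene that expresses Cre recombinase in the developing lens. The control group, LeCre, carried the transgene alone. The other groups were in addition homozygous for floxed alleles of Fgfr2, of Pten, or of both genes (Fgfr2Pten). Fgfr2 encodes a receptor for fibroblast growth factors (FGF), and Pten a lipid phosphatase that opposes PI3K signalling. Each group had 3 libraries, called pools 1 to 3 here, and values are given as mean FPKM ± SD with n = 3 pools. Fold changes are given on the log2(FPKM + 1) scale ± SE, with the adjusted p of limma. The median locus stood at 16.1 to 17.1 FPKM in every library, and the depth behind these values is unknown.

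Transcripts of the targeted genes were examined first. The most abundant of the 10 tested loci of Fgfr2 (chromosome 7, 130162451-133123350) had 51.4, 43.8 and 47.2 FPKM in the Fgfr2 pools. LeCre pools had 59.6, 67.1 and 73.1 FPKM, Pten pools 89.9, 99.8 and 101.9, and the pools labelled Fgfr2Pten 78.8, 103.6 and 95.2. In Fgfr2 against LeCre, 5 of the 10 loci fell, among them this one (-0.48 ± 0.11, limma adjusted p = 0.0129), whose call was lost without Fgfr2 pool 2 (0.0676) or LeCre pool 3 (0.0858). A further locus, which carries the symbols of both Ctbp2 and Fgfr2 and is not among the 10, was called higher (0.272 ± 0.078, limma adjusted p = 0.0473). In the libraries labelled Fgfr2Pten none of the 10 was called lower than in LeCre, and the most abundant was called higher (0.46 ± 0.11, adjusted p = 0.0272). In Pten lenses 3 of the 10 were called higher, among them the most abundant (0.54 ± 0.11, adjusted p = 0.0101; 0.0742 without LeCre pool 1). The Fgfr2Pten call was lost without Fgfr2Pten pool 2 (0.135), Fgfr2Pten pool 3 (0.0785), LeCre pool 1 (0.166) or LeCre pool 2 (0.0834). These loci cannot be tied to the exons that the floxed allele loses, so they do not check the Fgfr2 genotype of any library, and the group is called by its label here.

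The main Pten locus (chromosome 19, 32757497-32826160) had 45.5, 42.3 and 66.6 FPKM in the Pten pools and 53, 62.9 and 55.3 in those labelled Fgfr2Pten. LeCre pools had 80.3, 96.6 and 82.1 FPKM, and Fgfr2 pools 78.8, 64.9 and 88.2. Pten fell in the Pten group (-0.76 ± 0.15, limma adjusted p = 0.00824) and in the libraries labelled Fgfr2Pten (-0.59 ± 0.15, adjusted p = 0.04). The Pten call was lost without Pten pool 1 (0.0512) or LeCre pool 2 (0.0543). The call in the libraries labelled Fgfr2Pten was lost without any 1 pool of either group, or without Fgfr2 pool 1 (0.0626), with adjusted p up to 0.168 without LeCre pool 2.

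**Figure D1:**
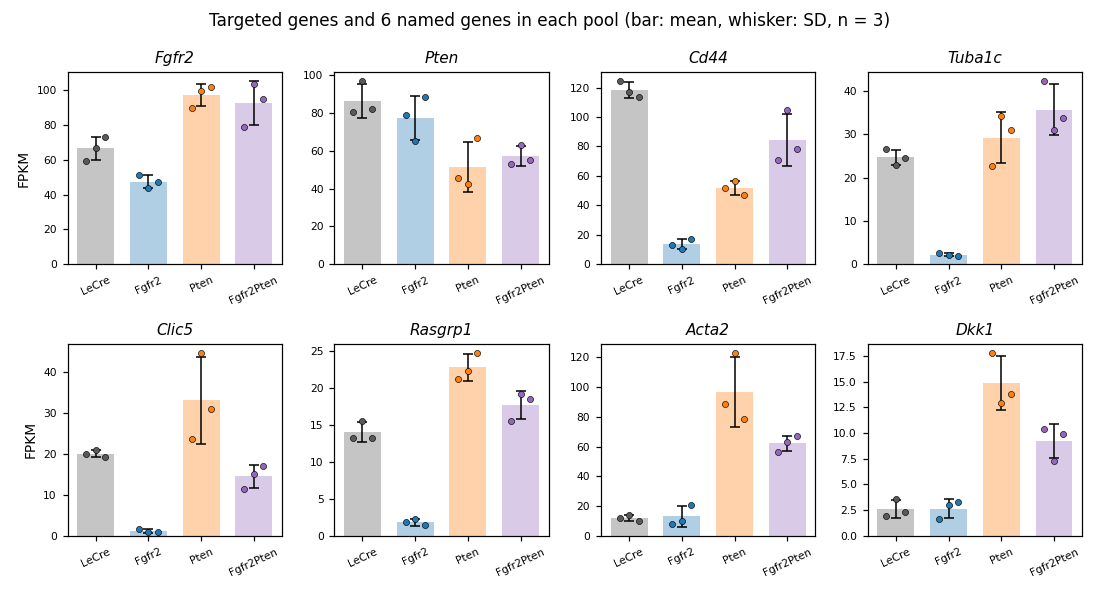
FPKM (vertical axes, linear) of Fgfr2, Pten and 6 named genes in the 4 groups; bars are group means, whiskers SD, and points the 3 pools. Cd44 stood at 118 ± 5.57 FPKM in LeCre and 13.7 ± 3.23 in Fgfr2, and Acta2 at 12 ± 2.11 in LeCre and 96.6 ± 23.5 in Pten.

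Genes of lens fiber differentiation were lower in Fgfr2 lenses than in LeCre lenses. Clic5, a chloride intracellular channel family member (chromosome 17, 44188584-44280172), fell from 20.0 ± 0.850 FPKM in LeCre to 1.20 ± 0.436 in Fgfr2 lenses (-3.27 ± 0.21, limma adjusted p = 2.36e-08). Dnase2b, the nuclease that degrades nuclear DNA in fiber cells, fell from 165 ± 7.73 to 67.2 ± 7.0 FPKM (-1.29 ± 0.09). Birc7, an inhibitor of apoptosis protein, fell by 0.80 and Tdrd7, a component of RNA granules needed for lens transparency, by 0.54 on the log2 scale. Of the 18 tested fiber genes other than crystallins, 9 fell and none rose, or 11 adjusted over the list alone. The list as a whole was lower by camera (adjusted p = 2.74e-08; adjusted p = 0.129 with an estimated correlation). Mip, the fiber cell aquaporin, did not pass the test (-0.20), nor did the gap junction gene Gja8 (0.21).

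Among the largest named falls in Fgfr2 lenses was Cd44, a hyaluronan receptor (chromosome 2, 102811141-102901665), from 118 ± 5.57 to 13.7 ± 3.23 FPKM (-3.04 ± 0.15, limma adjusted p = 9.46e-10). Tuba1c, an alpha-tubulin (chromosome 15, 99029891-99038110), fell from 24.7 ± 1.75 to 2.23 ± 0.321 FPKM (-2.99 ± 0.16). Rasgrp1, an activator of Ras (chromosome 2, 117279993-117343001), fell from 14.1 ± 1.33 to 1.83 ± 0.451 FPKM (-2.42 ± 0.15). The GTPase regulator Tbc1d30 (-2.13 ± 0.12), the stress response gene Gadd45a (-1.74 ± 0.22), the endocytic adaptor Pacsin3 (-1.68 ± 0.17) and the connexin Gjb6 (-1.59 ± 0.26) fell as well. The erythroid spectrin gene Spta1 fell from 19.2 ± 1.52 to 0.367 ± 0.153 FPKM and was at or below 0.5 FPKM in every Fgfr2 pool. It is 1 of the 15 all-or-none loci described in the closing part. For this locus genotype and mouse line cannot be told apart.

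Among FGF receptors, Fgfr1 fell in Fgfr2 lenses from 149 ± 0.503 to 53.3 ± 21.8 FPKM (-1.54 ± 0.23, limma adjusted p = 0.000438), with 1 rise, of Fgf1 (0.0664 without LeCre pool 1 and 0.0956 without LeCre pool 2), and 1 fall among the 6 tested FGF ligands and receptors. Targets induced by FGF and ERK signalling were not lower: 2 of 15 rose and none fell, or 4 rises adjusted over the list alone. The list was higher by camera (adjusted p = 0.0104; adjusted p = 0.342 with an estimated correlation). The risers were the ETS factors Etv4 and Etv5. Etv4 passed in the full set (adjusted p = 0.0232) but not without Fgfr2 pool 1 (0.0788) or 3 (0.0781) or LeCre pool 2 (0.111) or 3 (0.0766). Etv5 passed (adjusted p = 0.0217) but not without Fgfr2 pool 2 (0.0563) or 3 (0.0842) or LeCre pool 2 (0.092) or 3 (0.0866). BMP targets were higher as a list (camera adjusted p = 0.00106; adjusted p = 0.204 with an estimated correlation), with 1 of 10 called, Id1 (0.0536 without Fgfr2 pool 2), and 5 adjusted over the list alone. Wnt feedback targets were also higher (adjusted p = 0.0207; adjusted p = 0.592 with an estimated correlation; 0.188 without LeCre pool 3). Nkd1, an inhibitor of Wnt signalling, rose from 6.93 ± 0.839 to 23.4 ± 2.99 FPKM and was the only call among the 8. Sesn1, a FOXO and p53 target (-0.85 ± 0.10), and the replication clamp gene Pcna (-0.98 ± 0.11) fell.

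Some markers of other tissues rose in the same comparison. The collagen genes Col1a1 (from 0.10 ± 0 to 4.70 ± 2.85 FPKM) and Col1a2 (from 5.03 ± 0.404 to 10.5 ± 1.27) rose in Fgfr2 lenses, and the 5 tested mesenchyme markers were higher as a list. That list had a camera adjusted p of 0.0104 (adjusted p = 0.525 with an estimated correlation; 0.274 without Fgfr2 pool 2). The pigment cell gene Tyrp1 stood at 9.20 ± 3.49 FPKM against 3.70 ± 1.78, and its limma call (adjusted p = 0.0348) was lost without Fgfr2 pool 1 (0.188), LeCre pool 1 (0.0597) or LeCre pool 3 (0.186). The pigment list had a camera adjusted p of 0.135 (0.0285 without LeCre pool 2) and the retina and neuron list 0.291, with none of its 4 genes called. Rtn1, a neuronal reticulon, rose from 2.43 ± 0.351 to 41.9 ± 14.9 FPKM. Endothelial markers had a median change of -0.04, with none of 9 called.

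In total, 972 of 14806 loci were called in Fgfr2 against LeCre, 418 higher and 554 lower, by limma. The count was 607 without Fgfr2 pool 1, 640 without Fgfr2 pool 2, 589 without LeCre pool 3 and 581 with the level of the Y-linked gene Eif2s3y as a covariate. It was 1940 with the first axis of the within-group deviations as a covariate, an axis estimated from the residuals of these same values; both covariates were chosen after seeing the data.

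Genes of glycolysis and the hypoxia response were higher in Pten lenses than in LeCre lenses. Bnip3, a mitochondrial protein induced by hypoxia (chromosome 7, 138890836-138909519), rose from 165 ± 4.87 FPKM in LeCre to 378 ± 6.71 in Pten lenses (1.20 ± 0.10, limma adjusted p = 2.24e-06). The glycolytic kinase gene Pgk1 rose from 240.1 ± 17.0 to 362 ± 36.9 FPKM (0.59 ± 0.11). Of the 19 tested members of this list, 7 rose and none fell, or 12 rises adjusted over the list alone (camera adjusted p = 3.08e-11; adjusted p = 0.18 with an estimated correlation). Bnip3 and Aldoa lie within 10 Mb of Fgfr2, and Pgam1 within 10 Mb of Pten. Slc2a1, the main glucose transporter of the list, did not pass (1457 ± 196 FPKM against 1533 ± 68.4).

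Apart from the pseudogenes and copied loci described last, the largest named rise in Pten lenses was that of Acta2, smooth muscle actin (chromosome 19, 34241090-34255590), from 12 ± 2.11 to 96.6 ± 23.5 FPKM (2.90 ± 0.24, limma adjusted p = 1.88e-06). It was the only call among 12 tested genes of epithelial-mesenchymal transition and the TGF-beta response (camera adjusted p = 0.118; 0.0409 without Pten pool 1), or 3 adjusted over the list alone. Dkk1, a secreted Wnt antagonist, rose from 2.60 ± 0.889 to 14.8 ± 2.61 FPKM, and the glutamate transporter gene Slc1a1 from 0.633 ± 0.404 to 5.83 ± 1.77. Acta2, Dkk1 and Slc1a1 all lie within 10 Mb of Pten. Ccdc117 (chromosome 11, 5528887-5542187) rose from 98.5 ± 2.13 to 437 ± 72.8 FPKM and the vasopressin gene Avp from 2.30 ± 0.400 to 13.8 ± 5.75. Elavl4, a neuronal RNA-binding protein, rose from 5.03 ± 0.808 to 11.8 ± 0.321 FPKM, the only call among 4 tested retina and neuron markers (camera adjusted p = 0.304; 0.0305 without LeCre pool 2), also adjusted over the list alone.

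The amino acid response was higher in Pten lenses, with 3 of 14 tested ATF4 targets called, or 5 adjusted over the list alone (camera adjusted p = 0.00129; adjusted p = 0.18 with an estimated correlation). They were Sesn2, an inhibitor of mTORC1 (0.72 ± 0.11), Psat1 of serine synthesis (0.42 ± 0.07), and Chac1, which degrades glutathione (1.93 ± 0.551 FPKM against 0.10 ± 0.10). Notch pathway genes were lower as a list without any single call among 11, or 5 falls adjusted over the list alone. Their camera adjusted p was 6.58e-05 (adjusted p = 0.167 with an estimated correlation), and the most abundant, Jag1, stood at 914 ± 44.0 FPKM against 1093 ± 24.6. FGF and ERK feedback targets were lower as well (camera adjusted p = 0.00513; adjusted p = 0.201 with an estimated correlation), with 1 of 15 called, or 2 adjusted over the list alone. That call was Myc (-0.96 ± 0.19), lost without LeCre pool 3 (0.0521). Fiber genes were higher as a list with none called among 18 and 3 adjusted over the list alone (camera adjusted p = 0.00865; adjusted p = 0.355 with an estimated correlation; 0.148 without Pten pool 2).

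Among the largest named falls in Pten lenses were those of Sgip1, an endocytic regulator (from 9.63 ± 2.76 to 1.10 ± 0.265 FPKM), and Pbld2 (from 19.3 ± 2.35 to 4.50 ± 0.755). The guanine nucleotide exchange factor gene Dock9 fell from 43.4 ± 4.12 to 13.2 ± 2.50 FPKM (-1.65 ± 0.14, limma adjusted p = 1.68e-06). The adaptor Sh3kbp1 (-1.31 ± 0.14), the chloride channel Ano1 (-1.29 ± 0.12), Tagap1 (-1.37 ± 0.18), Egfem1 (-1.29 ± 0.20) and the cornified envelope gene Scel (-1.24 ± 0.23) fell too. Cd44 fell in this group as well, to 51.6 ± 4.75 FPKM (-1.18 ± 0.15). Lamc1, a laminin chain of the lens capsule, fell (-0.41 ± 0.08), and the BMP target Msx2 rose (0.86 ± 0.15).

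In total, 428 loci were called in Pten against LeCre by limma, 275 higher and 153 lower. The count was 285 without Pten pool 1, 256, 268 and 236 without LeCre pool 1, 2 and 3, and 149 with the level of the Y-linked gene Eif2s3y as a covariate. It was 795 with the first within-group axis as a covariate.

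Among the 18 tested fiber genes, 11 stood above LeCre in lenses labelled Fgfr2Pten and 2 were called (camera adjusted p = 0.178). Caprin2, an RNA-binding protein of fiber cells (chromosome 6, 148842492-148896237), rose from 2752 ± 50.2 FPKM in LeCre to 4257 ± 404 (0.62 ± 0.11, limma adjusted p = 0.00408). Clic5 stood at 14.5 ± 2.79 FPKM against 20.0 ± 0.850, and Dnase2b at 158 ± 5.75 against 165 ± 7.73. The called genes were Caprin2 and Birc7 (the latter 0.0523 without LeCre pool 1); none fell, and the counts were the same adjusted over the list alone.

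Glycolysis and hypoxia genes were higher in these libraries, with 8 rises and no falls among 19, or 13 rises adjusted over the list alone (camera adjusted p = 2.03e-13; adjusted p = 0.117 with an estimated correlation). Bnip3 reached 350.5 ± 43.8 FPKM (1.08 ± 0.10), P4ha1, a collagen prolyl hydroxylase, 1559.5 ± 239.9 (0.68 ± 0.11), and the aldolase gene Aldoa 946 ± 189 (0.63 ± 0.12). ATF4 targets were higher, with 4 of 14 called, or 6 adjusted over the list alone (camera adjusted p = 1.08e-06; adjusted p = 0.103 with an estimated correlation). Slc7a11, the cystine transporter (chromosome 3, 49892526-50443614), rose from 39.3 ± 9.10 to 114 ± 33.4 FPKM (limma adjusted p = 0.000303), Sesn2 from 22.5 ± 2.88 to 46.1 ± 2.85, and Chac1 from 0.10 ± 0.10 to 2.70 ± 0.819.

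Targets of p53 and apoptosis genes were higher in the libraries labelled Fgfr2Pten, with 6 rises and 1 fall among 15, or 9 and 1 adjusted over the list alone. The camera adjusted p was 8.41e-07 (adjusted p = 0.117 with an estimated correlation). In Pten lenses this list had 2 rises and 2 falls, or 5 and 2 adjusted over the list alone. Its camera adjusted p there was 0.0716 (0.0495 without Fgfr2 pool 3, 0.0358 without Pten pool 1 and 0.0379 without LeCre pool 1). In Fgfr2 lenses it had 1 rise, also adjusted over the list alone (camera adjusted p = 0.605). Cdkn1a, a cyclin-dependent kinase inhibitor, rose from 18.2 ± 0.513 to 36.1 ± 4.20 FPKM (0.95 ± 0.15, limma adjusted p = 0.00169), and cyclin G1 (Ccng1) from 341 ± 20.5 to 586 ± 35.5 (0.78 ± 0.15). Cholesterol synthesis genes were higher as a list, with 17 of 18 fold changes above 0 and 1 called, or 5 adjusted over the list alone (camera adjusted p = 6.12e-05; adjusted p = 0.208 with an estimated correlation). That call was Fdft1, squalene synthase (limma adjusted p = 0.0201), lost without Fgfr2Pten pool 1 (0.0518) or 3 (0.0774) or LeCre pool 1 (0.0976), 2 (0.0681) or 3 (0.0535).

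Notch genes were lower in the same libraries, with 2 of 11 called and as many adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.208 with an estimated correlation). These were the receptor gene Notch3 (-0.74; 0.0547 without LeCre pool 2) and the target gene Heyl (-0.91; 0.11 without Fgfr2Pten pool 1, 0.121 without LeCre pool 1 and 0.103 without LeCre pool 2). FGF ligands and receptors were lower, with 1 of 6 called, or 3 adjusted over the list alone (camera adjusted p = 0.00576; adjusted p = 0.117 with an estimated correlation). The called gene, Fgfrl1, a receptor without a kinase domain (limma adjusted p = 0.0439), was lost without any of 9 of the 12 libraries (0.0531 to 0.18). Another of the 6, Fgf15, is also among the retina and ciliary body genes described below. It stood at 0.5 FPKM against 3.7 in LeCre and was not called (limma adjusted p = 0.0584), a value named after it was seen. Endothelial markers were lower as a list with none of 9 called or called adjusted over the list alone (camera adjusted p = 0.0319; adjusted p = 0.746 with an estimated correlation). That list call was lost without Fgfr2Pten pool 1 (0.712), LeCre pool 1 (0.0799) or LeCre pool 2 (0.112).

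Several large changes of single genes against LeCre in these libraries were also called in Pten lenses. Acta2 rose to 62.1 ± 5.25 FPKM (2.29 ± 0.24) and Ccdc117 to 413 ± 66.9 (2.05 ± 0.13), while Pbld2 fell to 4.63 ± 0.416 (-1.85 ± 0.16) and Dock9 to 13.6 ± 1.21 (-1.61 ± 0.14). Elavl4 rose to 14.9 ± 3.10 FPKM (1.39 ± 0.17). Spta1, low in Fgfr2 lenses, fell here too, to 1.70 ± 1.25 FPKM (-3.02 ± 0.26). Scfd2, of the Sec1 family, rose from 17.3 ± 1.47 to 67.2 ± 22.9 FPKM (1.85 ± 0.17), Ociad2 from 4.63 ± 2.06 to 21.1 ± 10.2, and the recombination gene Rdm1 from 9.0 ± 1.04 to 37.3 ± 9.06. Psmc3ip (-1.57 ± 0.20), the ribosomal protein gene Rpl26 (-1.53 ± 0.28), the heparan sulfate sulfotransferase gene Hs3st2 (-1.49 ± 0.20) and Cacng4 (-1.30 ± 0.24) fell. Of these, Hs3st2 lies within 10 Mb of Fgfr2.

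In total, 496 loci were called in Fgfr2Pten against LeCre by limma, 308 higher and 188 lower, a split of 221 and 214 under a TPM scaling. The count was 290 without Fgfr2Pten pool 2, 236, 273 and 302 without LeCre pool 1, 2 and 3, and 244 with the level of the Y-linked gene Eif2s3y as a covariate. It was 1113 with the first within-group axis as a covariate.

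**Figure D2:**
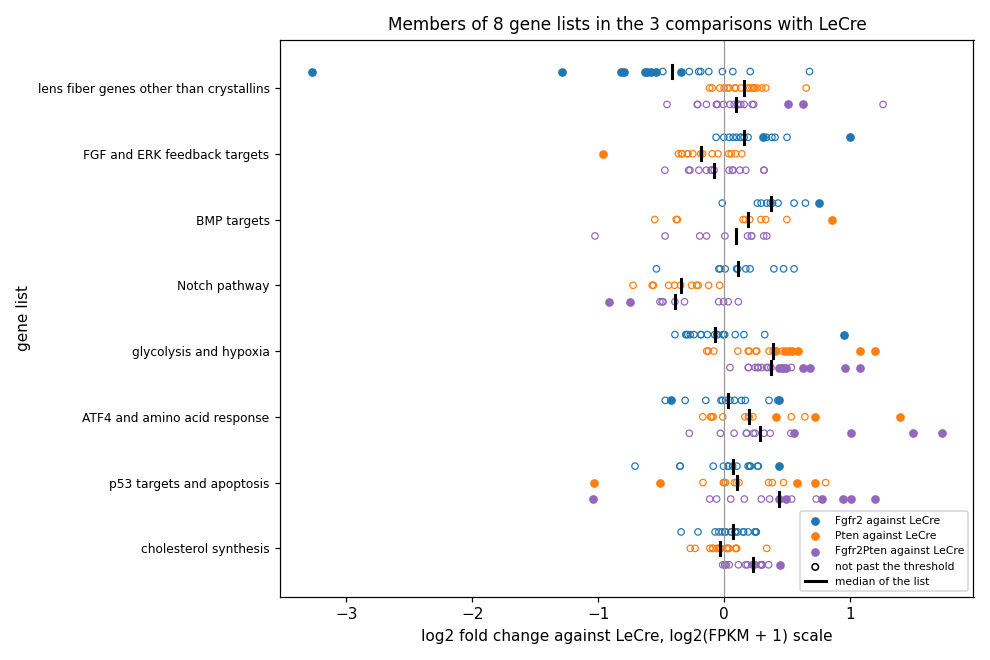
Log2 fold change against LeCre (horizontal axis, log2(FPKM + 1) scale) of each tested member of 8 gene lists, in Fgfr2, Pten and Fgfr2Pten; filled points were called, open points were not, and black bars mark list medians. The median fiber gene stood at -0.42 in Fgfr2, 0.16 in Pten and 0.09 in Fgfr2Pten, and the median glycolysis and hypoxia gene at -0.07, 0.39 and 0.37.

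The libraries labelled Fgfr2Pten were next compared with Fgfr2 lenses, from which they differ by label in the floxed Pten alleles. They differed in Fgfr2 transcripts as well, with 6 of the 10 Fgfr2 loci called higher, of which 4 held without any 1 library. Fiber genes were higher than in Fgfr2 lenses, with 9 of 18 rising and none falling, or 10 rising and 1 falling adjusted over the list alone (camera adjusted p = 2.55e-09; adjusted p = 0.102 with an estimated correlation). Clic5 (2.82 ± 0.21), Birc7 (1.31 ± 0.10), Dnase2b (1.23 ± 0.09) and Tdrd7 (0.76 ± 0.09) rose. So did Tuba1c (3.50 ± 0.16, limma adjusted p = 5e-10), Rasgrp1 (2.73 ± 0.15), Cd44 (2.55 ± 0.15) and Ccdc117 (2.81 ± 0.13).

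Lists of glycolysis, ATF4 targets, p53 targets and cholesterol synthesis were higher than in Fgfr2 lenses. Glycolysis and hypoxia genes had 12 rises among 19, or 13 adjusted over the list alone (camera adjusted p = 1.6e-09; adjusted p = 0.16 with an estimated correlation), led by Bnip3 (1.35 ± 0.10) and P4ha1 (0.98 ± 0.11). ATF4 targets had 5 rises among 14 with as many adjusted over the list alone (7.79e-05; adjusted p = 0.129 with an estimated correlation), among them the asparagine synthetase gene Asns (0.87 ± 0.15). Targets of p53 had 5 rises among 15, or 8 adjusted over the list alone (0.00137; adjusted p = 0.207 with an estimated correlation), including the proapoptotic gene Pmaip1 (1.55 ± 0.29). Cholesterol synthesis had 2 rises among 18, or 6 adjusted over the list alone. Its camera adjusted p was 0.0219 (adjusted p = 0.368 with an estimated correlation; 0.17 without Fgfr2Pten pool 1 and 0.0512 without Fgfr2Pten pool 3). Stress and immediate early genes had 1 rise, Dnajb1, and 1 fall, Junb, among 7 (camera adjusted p = 0.852), and each call was lost in some fits without 1 library (up to 0.199 and 0.101 without Fgfr2 pool 1).

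Lists of BMP, Wnt, Notch and FGF feedback genes were lower than in Fgfr2 lenses, while FGF ligands and receptors did not pass (camera adjusted p = 0.114). BMP targets had 4 falls among 10, or 5 adjusted over the list alone (camera adjusted p = 0.00322; adjusted p = 0.16 with an estimated correlation), and Id3 fell from 206 ± 42.8 to 132 ± 9.50 FPKM. Wnt feedback targets had 3 falls among 8, or 4 adjusted over the list alone (0.00598; adjusted p = 0.341 with an estimated correlation), including the transcription factor Tcf7 (-0.66 ± 0.15). Notch genes had 2 falls among 11, or 6 adjusted over the list alone (0.00322; adjusted p = 0.16 with an estimated correlation), the receptor gene Notch3 (-0.71 ± 0.15) and the ligand gene Jag2 (-0.96 ± 0.20). FGF and ERK feedback targets had 1 fall among 15, or 4 adjusted over the list alone, and that was Etv4 (-1.28 ± 0.25). Their camera adjusted p was 0.0133 (adjusted p = 0.207 with an estimated correlation; 0.127 without Fgfr2Pten pool 3).

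Genes of lens transcription factors, of the lens capsule and of lens epithelium went both ways against Fgfr2 lenses, and none of the 3 lists passed. Lens transcription factors had 3 rises and 4 falls among 16, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.348). Pax6 fell from 261 ± 27.0 to 181 ± 23.0 FPKM (-0.52 ± 0.10), and Maf, an activator of crystallin genes, rose (0.42 ± 0.09). Lens capsule and basement membrane genes had 2 rises and 6 falls among 17, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.203; 0.0322 without Fgfr2 pool 3). Lens epithelium genes had 3 rises and 2 falls among 9, with the same counts adjusted over the list alone (camera adjusted p = 0.958). FOXO targets had 2 rises and 3 falls among 18, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.366). Genes of epithelial-mesenchymal transition had 4 rises and no fall among 12, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.22).

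Mesenchyme and pigment cell markers were lower in the libraries labelled Fgfr2Pten than in Fgfr2 lenses (camera adjusted p = 0.0137 and 0.0343; adjusted p = 0.341 and 0.368 with an estimated correlation), and other tissue lists did not pass. Col1a1 (-2.19 ± 0.31), Tyrp1 (-1.72 ± 0.31) and Rtn1 (-2.94 ± 0.23) fell. Of 4 retina and neuron markers, 1 rose, Elavl4 (1.18 ± 0.17), and 2 fell, Vsx2 (-2.11 ± 0.44) and Six6 (-1.38; lost without any 1 pool of either group except Fgfr2 pool 3, up to 0.153 without Fgfr2 pool 2), as also adjusted over the list alone (camera adjusted p = 0.372). Endothelial markers (camera adjusted p = 0.22; 0.00474 without Fgfr2Pten pool 2) and macrophage and leukocyte markers (0.122; 0.0187 without Fgfr2Pten pool 2) had no call among 9 and 3. Mesenchyme markers had 2 falls among 5, or 3 adjusted over the list alone, and the list call was lost without Fgfr2 pool 2 (camera adjusted p = 0.287) or Fgfr2Pten pool 1 (0.0655). Pigment cell markers had 3 falls among 5, or 4 falls and 1 rise adjusted over the list alone. The camera call of that list was lost under a TPM scaling (0.0506) and without Fgfr2 pool 1 (0.257) or 2 (0.0719), Fgfr2Pten pool 1 (0.0555) or 3 (0.0512), or LeCre pool 2 (0.0666).

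This contrast had the largest count of the 6, with 1896 loci called by limma, 1056 higher and 840 lower, a split of 824 and 1053 under a TPM scaling. The count was 1056 without Fgfr2 pool 1, 1059 without Fgfr2 pool 2 and 1098 without Fgfr2Pten pool 2. It was 3301 with the first within-group axis as a covariate.

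The libraries labelled Fgfr2Pten were also compared with Pten lenses, from which they differ by label in the floxed Fgfr2 alleles. The most abundant Fgfr2 locus stood at 78.8, 103.6 and 95.2 FPKM against 89.9, 99.8 and 101.9 in Pten pools, and 1 of the 10 Fgfr2 loci was called lower (limma adjusted p = 0.0274; 0.0559 to 0.121 without any of 5 libraries). A loss of Fgfr2 in these libraries could thus not be checked. Slc7a11 was higher in the former (1.60 ± 0.20, limma adjusted p = 0.000253), as were Perp, a p53 target of cell adhesion (0.95 ± 0.11), Sgip1 (2.28 ± 0.26), Ociad2 (2.05 ± 0.28) and Scfd2 (1.89 ± 0.17). Spta1 was lower (-3.82 ± 0.26). Clic5 fell from 33.1 ± 10.8 to 14.5 ± 2.79 FPKM (-1.10 ± 0.21), a call lost without Pten pool 2 (0.053) or Fgfr2Pten pool 1 (0.0561).

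Cholesterol synthesis genes were higher than in Pten lenses, with 16 of 18 fold changes above 0 and 1 called, or 3 adjusted over the list alone (camera adjusted p = 5.79e-06; adjusted p = 0.317 with an estimated correlation). Targets of p53 were higher with 1 of 15 called and as many adjusted over the list alone (0.000467; adjusted p = 0.317 with an estimated correlation). FGF and ERK feedback targets were higher with none of 15 called and 3 adjusted over the list alone (0.00382; adjusted p = 0.317 with an estimated correlation; 0.0738 without Fgfr2Pten pool 2). Lens epithelium genes were lower with none of 9 called, nor any adjusted over the list alone (0.00487; adjusted p = 0.43 with an estimated correlation; 0.104 without Fgfr2Pten pool 2). Endothelial markers were lower with none of 9 called, nor any adjusted over the list alone (0.00382; adjusted p = 0.479 with an estimated correlation; 0.0683 without Pten pool 3 and 0.5 without Fgfr2Pten pool 1).

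By limma 196 loci were called, 86 higher and 110 lower. The count was 88 when only these 2 groups were fitted, 90 without Pten pool 1, 100 without Fgfr2Pten pool 2, and 530 with the first within-group axis as a covariate.

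The interaction asked whether the change in libraries labelled Fgfr2Pten differed from the sum of the single changes. Cd44 fell in both single mutants but stood at 84.7 ± 17.6 FPKM in these libraries, above that sum by 3.73 ± 0.21 (limma adjusted p = 7.9e-09). Tuba1c (3.28 ± 0.22), Sgip1 (3.19 ± 0.37), Tagap1 (2.51 ± 0.26) and Clic5 (2.17 ± 0.29) were above the sum too. Among fiber genes, 4 of 18 lay above it and none below, or 8 adjusted over the list alone (camera adjusted p = 1.07e-06; adjusted p = 0.116 with an estimated correlation), with Dnase2b at 0.96 ± 0.12 and Birc7 at 0.98 ± 0.14. Gadd45a (1.56 ± 0.32), Pcna (0.91 ± 0.16) and Perp (0.95 ± 0.16) were also above the sum.

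BMP targets lay below the sum, with 3 of 10 called, or 4 adjusted over the list alone (camera adjusted p = 0.000127; adjusted p = 0.116 with an estimated correlation). Wnt feedback targets were below it with none of 8 called, nor any adjusted over the list alone (0.00818; adjusted p = 0.661 with an estimated correlation; 0.0724 without LeCre pool 3). Mesenchyme markers were below it with 1 of 5 called, Col1a1 (-2.40 ± 0.43), or 3 adjusted over the list alone (0.00642; adjusted p = 0.661 with an estimated correlation; 0.132 without Fgfr2 pool 2). Cholesterol synthesis (above) and pigment cell markers (below) passed narrowly, both at 0.0487, with none called in either; adjusted over the list alone, 0 cholesterol genes and 1 pigment marker were called. Their adjusted p was 0.668 with an estimated correlation and 0.0631 under a TPM scaling. The cholesterol call was lost without Fgfr2 pool 1 (0.059) or 3 (0.0714), Pten pool 1 (0.0603), Fgfr2Pten pool 1 (0.24) or 3 (0.115), or LeCre pool 3 (0.189). The pigment call was lost without Fgfr2 pool 1 (0.264) or 2 (0.0797), Pten pool 1 (0.0574) or 3 (0.128), Fgfr2Pten pool 1 (0.0636) or 3 (0.0758), or LeCre pool 1 (0.0819) or 3 (0.189).

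In all, 352 loci passed the interaction test by limma, 194 above the sum and 158 below. The count was 211 without Fgfr2 pool 1, 232 without Fgfr2Pten pool 2, 218 without LeCre pool 3, and 178 with the level of the Y-linked gene Eif2s3y as a covariate. It was 1003 with the first within-group axis as a covariate.

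Changes in Pten lenses and in the libraries labelled Fgfr2Pten overlapped. Against LeCre, 122 loci rose in both, 55 fell in both and 3 went opposite ways, where independent lists would share 5.69, 1.92 and 6.62. Across 14795 loci, which are not independent replicates, the fold changes correlated with r = 0.61, against 0.50 for unchanged groups simulated with the shared LeCre pools. Their covariance was 0.0575, against 0.0182 simulated. For Fgfr2 and Fgfr2Pten, 87 loci rose in both, 72 fell in both and 24 were opposite (8.57, 6.94 and 16.6 for independent lists), with r = 0.32 (0.503 simulated) and a covariance of 0.0371 (0.0183 simulated). For Fgfr2 and Pten the counts were 82, 35 and 50 (7.65, 5.71 and 14.5 for independent lists), with r = 0.285 (0.505 simulated) and a covariance of 0.0313 (0.0184 simulated). With 3 LeCre pools no split leaves 2 in each part, so some of the excess over independent lists may come from the shared controls.

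The comparison of Fgfr2 with LeCre and that of Fgfr2Pten with Fgfr2 shared the Fgfr2 pools, and 590 loci were called in opposite directions in them, against 6 that rose in both and 2 that fell in both. Independent lists would give 62.7, 29.5 and 31.2, but the Fgfr2 pools enter both comparisons, with opposite signs. Some of the excess of opposite calls may therefore come from these shared pools. The fold changes of both comparisons had an r of -0.665 (-0.501 simulated) and a covariance of -0.0979 (-0.0183 simulated). Fgfr2 against LeCre and Fgfr2Pten against Pten, which share no libraries, gave r = 0.058 (jackknife SE 0.12), where 30 loci rose in both, 41 fell in both and 35 were opposite (2.37, 3.99 and 6.16 for independent lists). The Fgfr2 genotype of the libraries labelled Fgfr2Pten was unchecked in both this and the next comparison. For Pten against LeCre and Fgfr2Pten against Fgfr2, r was 0.219 (jackknife SE 0.121), and the counts were 124, 63 and 45 (19.5, 8.65 and 26.4 for independent lists).

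Crystallins, the main structural proteins of the lens, were tested in 9 loci. Crygf fell in Fgfr2 lenses from 5759.6 ± 846 to 2802 ± 404 FPKM (-1.04 ± 0.21, limma adjusted p = 0.00601), the only call against LeCre in any mutant, also adjusted over the list alone, but an uncertain one since Crygf has near-identical copies. The list's camera adjusted p was 0.0726 in Fgfr2, 0.971 in Pten and 0.915 in Fgfr2Pten. In Fgfr2 the list passed without Fgfr2 pool 2 (0.0199), Pten pool 3 (0.0411) or LeCre pool 2 (0.0285). Against Fgfr2 lenses 3 of the 9 rose in the libraries labelled Fgfr2Pten and none fell, also adjusted over the list alone. The camera adjusted p was 0.114 (0.0263 without Fgfr2 pool 2, 0.0461 and 0.0419 without Fgfr2Pten pool 1 and 2). They were Cryba2 (0.44; 0.0515 to 0.145 without any of 5 libraries), Crygf (0.79; 0.113 without Fgfr2 pool 1 and 0.0805 without Fgfr2Pten pool 3) and Crygs (0.62; 0.0728 and 0.0916 without Fgfr2 pool 1 and 2, 0.0908 without Fgfr2Pten pool 2). Crygs also lay above the sum in the interaction (0.91, limma adjusted p = 0.0453; 0.0506 to 0.136 without any of 9 libraries), where the list's camera adjusted p was 0.203 (0.00917 without Pten pool 2). None of the 9 was called in Fgfr2Pten against Pten (0.848). A second, less abundant Crygs locus at the same place was not in the list. It stood at 720.5, 728.4 and 850.7 FPKM in Fgfr2 pools and 667, 841 and 831.7 in LeCre pools. Pten pools had 747.4, 907.7 and 766.5 FPKM there, and Fgfr2Pten pools 932.1, 1065.9 and 959.4. A fall in Fgfr2 lenses was thus not seen at this locus. Of the gamma-crystallin cluster on chromosome 1, 4 loci were kept out of the list, since they were listed at 0 in some libraries. Cryge and the locus of Cryga stood at 6416, 7841 and 7521 and at 37684, 40407 and 46632 FPKM in the Fgfr2 pools and were listed at 0 in the other 9 libraries. Crygd and the locus of Crygb and Crygc were listed at 0 in Pten pools 1 and 2, Fgfr2Pten pool 3 and LeCre pool 1, with 9532 to 20195 and 14650.4 to 27894 FPKM in the other libraries. The copies of Crygf lie in this cluster, and reads may be shared among them, so its values and both of its calls are uncertain. It was lowest in the Fgfr2 pools (2374, 3178 and 2855 FPKM), the only libraries with Cryge and Cryga above 0. It stood at 7257, 7400 and 6227 FPKM in Pten pools 1 and 2 and Fgfr2Pten pool 3, where Crygd was listed at 0, and at 3928, 4110 and 4383 in the other pools of these groups. In LeCre it was 6156 FPKM in pool 1, where Crygd was listed at 0, and 4788 and 6334 in pools 2 and 3.

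The remaining lists gave few calls against LeCre, and camera called none of them in those comparisons. Among 9 lens epithelium genes, 2 fell in Fgfr2 lenses, as many adjusted over the list alone, the sulfatase gene Sulf1 (-0.53 ± 0.08) and the cadherin gene Cdh1 (0.104 without Fgfr2 pool 1, 0.112 without Fgfr2 pool 3, 0.125 without LeCre pool 1 or 3), and none was called in Pten or Fgfr2Pten. Among 16 lens transcription factors, Maf fell in Fgfr2 lenses, also adjusted over the list alone (0.0682 without Fgfr2 pool 1 and 0.0732 without LeCre pool 1), and none was called in Pten or Fgfr2Pten. FOXO targets had 2 falls among 18 in Fgfr2, Sesn1 and Gadd45a, or 3 adjusted over the list alone, and none in Pten or Fgfr2Pten. Of 24 cell cycle genes, Pcna fell in Fgfr2, and Ccne1 rose in Pten (0.0606 without LeCre pool 3) and in Fgfr2Pten (0.0545 to 0.122 without any 1 pool of either group), or 2 rises and 1 fall in Pten adjusted over the list alone. Of 5 cyclin-dependent kinase inhibitors, none was called in Fgfr2, though 1 was adjusted over the list alone, and Cdkn1a rose in Fgfr2Pten and in Pten, the latter lost without any of 9 of the 12 libraries (0.0549 to 0.191). Of 17 lens capsule and basement membrane genes, 2 rose in Fgfr2, Lamc1 fell in Pten and 1 fell in Fgfr2Pten. The risers were Lamc1 (0.0747 and 0.0825 without Fgfr2 pool 1 and 2, 0.0663 and 0.0808 without LeCre pool 2 and 3) and Lama5 (0.0971 and 0.069 without Fgfr2 pool 1 and 2, 0.0638 without LeCre pool 3). In Fgfr2Pten it was Agrn, or agrin (0.0907 and 0.074 without Fgfr2Pten pool 1 and 2, 0.0993 and 0.111 without LeCre pool 1 and 2). Adjusted over the list alone the counts were 5 rises and 2 falls, 4 falls and 1 fall. None of 7 stress and immediate early genes was called in the 3 mutants, or 1 rise and 1 fall in Fgfr2 adjusted over the list alone. The retina and neuron list had a camera adjusted p of 0.291 in Fgfr2, and macrophage and leukocyte markers 0.0711 (0.043 without Fgfr2 pool 1, 0.0491 without Fgfr2Pten pool 1, 0.0319 without LeCre pool 1, 0.0382 with a replicate block), with none of 3 called but 3 rises adjusted over the list alone. The capsule list had a camera adjusted p of 0.0726 in Fgfr2 (0.00683 without Fgfr2 pool 3) and 0.232 in Pten (0.0224 without Pten pool 2). The erythroid markers tested, Hba-a1 and Hbb-bs, and the single cornea marker, Krt18, were not called in Fgfr2, Pten or Fgfr2Pten against LeCre.

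Sex-linked transcripts differed between the pools. Transcripts of the Y-linked gene Eif2s3y stood at 0.2 FPKM in Fgfr2Pten pool 1, 0.1 in LeCre pool 1 and 0 in LeCre pool 3, and between 42.2 and 179.7 in the other 9 libraries. The locus of Xist, the RNA of the inactive X chromosome, stood at 1.6 FPKM in Pten pool 3 and 0.8 in Fgfr2Pten pool 2, and between 502 and 2760.1 elsewhere. Pools with almost no Eif2s3y were thus found only in LeCre and Fgfr2Pten, and pools with almost no Xist only in Pten and Fgfr2Pten. Sex-linked transcripts were therefore not balanced between the groups. None of the 5 sex-linked loci passed the limma test in the 3 comparisons with LeCre, where the lowest adjusted p was 0.141, for Eif2s3y in Pten. With so wide a spread within groups, this test says little about sex makeup, but the values of single pools show that it differed. LeCre pools 1 and 3 had almost no Eif2s3y beside 2141.7 and 1607.6 FPKM at the Xist locus. Every Fgfr2 pool had at least 42.2 FPKM of Eif2s3y. Pten pool 3 and Fgfr2Pten pool 2 had almost no Xist beside 154.6 and 179.7 FPKM of Eif2s3y.

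Pseudogenes and loci with near-identical copies gave some of the largest changes, and their reads may be shared with the copies, so their values are uncertain. Vcp-rs (X chromosome, 104345829-104348234) stood at 0.133 ± 0.115 FPKM in LeCre and 40.4 ± 1.40, 41.0 ± 5.30 and 43.4 ± 4.84 in Fgfr2, Pten and Fgfr2Pten. The named locus of Tmem181b-ps stood at 0.533 ± 0.416 FPKM in LeCre, 46.0 ± 5.16 in Fgfr2, 49.2 ± 2.54 in Pten and 0.900 ± 0.557 in Fgfr2Pten, and its neighbour Tmem181a at 32.2 ± 4.99, 164 ± 33.1, 178 ± 19.9 and 34.5 ± 3.06. Cwc22, a splicing factor gene whose locus includes Gm13727, stood at 20.0 ± 2.88 FPKM in LeCre and 602 ± 54.3, 560.3 ± 94.0 and 364 ± 71.3 in the mutants. Pkd1l1 stood at 1.60 ± 0.458 FPKM in LeCre and 23.2 ± 2.50, 23.3 ± 1.23 and 7.80 ± 6.73. Rps13-ps1 was high in Fgfr2 (22.4 ± 3.47 FPKM) and Fgfr2Pten (21.1 ± 5.93) and low in Pten (0.667 ± 0.379) and LeCre (0.400 ± 0.200), while Eif5al3-ps had 28.3 to 32.4 FPKM in LeCre, 15.4, 16.6 and 0.4 in the Pten pools and at most 0.1 in Fgfr2 and Fgfr2Pten. Rps15a-ps8 had 33.8 to 38.1 FPKM in Fgfr2 and 44.0 to 65.6 in Fgfr2Pten, and was at 0.2 or less in Pten and LeCre pools.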

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

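The group contrasts, the interaction, the tests of the fixed gene lists and leaving out each library in turn were planned. The counts of splits and every other test in this part were chosen only after the result was seen, as were the retina and ciliary body genes named.

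The change in libraries labelled Fgfr2Pten differed from the sum of both single changes for 38 named loci, with limma adjusted p from 2.26e-12 to 0.0476. Values are differences from the sum of both single changes on the log2(FPKM + 1) scale. Of these loci, 23 lay above the sum: Cd44 (3.73), Tuba1c (3.28), Sgip1 (3.19), Tagap1 (2.51), Clic5 (2.17), Rasgrp1 (2.07), Scfd2 (1.97), Tacr3 (1.83), Gadd45a (1.56), Tbc1d30 (1.45), Dock9 (1.38), Slc7a11 (1.18), Egfem1 (1.16), Pacsin3 (0.99), Birc7 (0.98), Dnase2b (0.96), Perp (0.95), Ano1 (0.93), Pcna (0.91), Crygs (0.91), Sh3kbp1 (0.88), Sesn1 (0.69) and Tdrd7 (0.53). Below it lay 15: Tmem181b-ps (-9.73), the locus of Cwc22 and Gm13727 (-5.48), Vcp-rs (-5.12), Pkd1l1 (-4.99), Tmem181a (-4.64), the locus of Gm14296 and Mup-ps25 (-4.03), Rtn1 (-3.18), Col1a1 (-2.40), Fgf15 (-2.22), Txnip (-1.24), Nid2 (-1.21), Id1 (-0.91), Msx2 (-0.91), Id3 (-0.79) and Mafb (-0.63). The lowest adjusted p was that of Tmem181b-ps. Its values and those of Vcp-rs, Tmem181a, Pkd1l1 and the locus of Cwc22 and Gm13727 are uncertain, since reads may be shared with copies. Vcp-rs was low in LeCre alone and alike in the 3 mutants, which by itself gives a difference from the sum. For 25 of the 38 loci, those the naming rule took in this contrast, each library was left out in turn, and 14 held throughout. Leaving out LeCre pool 3 ended the largest number of calls (10 of 25), followed by Fgfr2 pool 1 and Pten pool 1 (9 each). Leaving out Fgfr2 pool 2, Fgfr2Pten pool 1 or 2 or LeCre pool 1 ended 8 each. These counts overlap, since 1 call can end in several of these fits.

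Other groupings of the samples were counted for each contrast. In the interaction, 1 of 100 drawn splits, the real one, gave as many loci (352, against at most 113 in the others). Drawn splits mix the 4 groups, whose own differences enter the spread and lower such counts, so these splits do not decide whether chance gave that count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. All but the real one mix both groups, whose difference enters the spread in the same way, so low counts there do not decide on chance either. The real split gave the highest count, 1 of 10, in Fgfr2 against LeCre (972, highest other 1), Pten against LeCre (428, highest other 0), Fgfr2Pten against LeCre (496, highest other 4) and Fgfr2Pten against Fgfr2 (1896, highest other 0). In Fgfr2Pten against Pten 2 of 10 splits gave as many as the real 196. The other one put Pten pools 1 and 2 and Fgfr2Pten pool 3 against the rest and gave 435, which points to a structure of the samples. Crygd and the locus of Crygb and Crygc were listed at 0 in these same 3 libraries and in LeCre pool 1.

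Called loci lay close to Pten. In Pten against LeCre 13 of 107 loci within 10 Mb of Pten were called, against 2.73% of loci elsewhere (one-sided Fisher's exact p = 9.07e-06). Fgfr2Pten against LeCre had 14 (13.08% against 3.28% elsewhere, Fisher's exact p = 1.33e-05). Fgfr2Pten against Fgfr2 had 28 (26.17% against 12.98%, 0.000203) and the interaction 8 (7.48% against 2.36%, 0.00422). Fgfr2Pten against Pten had 0 by limma, with 8 at an unadjusted p under 0.05. DNA of another strain linked to the Pten allele may give such calls. Neighbouring loci can share DNA and an assembled region, so they are not independent, as Fisher's test takes them to be. In Fgfr2 against LeCre, where Pten was not targeted, 16 of the 107 were called too (14.95% against 6.48% elsewhere, Fisher's exact p = 0.00156). Linked DNA and other differences between the lines thus cannot be told apart. Near Fgfr2, 18 of 207 loci were called in Fgfr2 against LeCre (8.7% against 6.52% elsewhere, Fisher's exact p = 0.134). Fgfr2Pten against LeCre had 15 (7.25% against 3.3%, 0.00431) and Fgfr2Pten against Pten 6 (2.9% against 1.24%, 0.0476). Pten against LeCre, where Fgfr2 was not targeted, had 11 (5.31% against 2.77%, 0.032). Fgfr2Pten against Fgfr2 had 23 (11.11% against 13.13%, 0.83) and the interaction 7 (3.38% against 2.39%, 0.231). Linked DNA near Fgfr2 is thus left open as well. An effect of Pten loss on these neighbours, such as Acta2, stays open and was not tested.

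A set of 15 loci is called all-or-none here. Each was at 5 FPKM or more in every library of 1 group and at 0.5 or less in every library of another. Of the 12 with an annotated type, 7 were pseudogenes, against 1.43% of the other tested loci (one-sided Fisher's exact p = 1.06e-10), as strain variants or copy number against the reference may give. Where Vcp-rs was high its parent Vcp stood lower by about what reads assigned to the copy would need (-0.22 ± 0.061 on the log2 scale, needed -0.27), but Tmem181a was higher where Tmem181b-ps was high (2.32), which argues against that source for this pair. Rps15a stood lower where Rps15a-ps8 was high by more than the copy's 45.4 FPKM would need (-1.28 ± 0.14, needed -0.39), which leaves reads moved to this copy and other causes of the fall that cannot be told apart. By group means, 9 of the 15 loci follow neither targeted gene's label across the 4 groups. Loss of a targeted gene stays open, since effects need not add up and the Fgfr2 genotype of the libraries labelled Fgfr2Pten is unchecked. The zeros listed for Cryge and Cryga leave it open as well. The other 6 all follow the Fgfr2 label, with Fgfr2 and Fgfr2Pten on 1 side and Pten and LeCre on the other. They are Eif5al3-ps, Gm10704, Gm10073, Gm11942, Spta1 and Rps15a-ps8. For these 6, genotype and mouse line cannot be told apart.

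Of 15 tested genes of retina and ciliary body, 2 rose in Fgfr2 against LeCre: Rbp3 (54.1 FPKM against 17.2 in LeCre, limma adjusted p = 1.91e-06, held without any 1 library) and Col2a1 (18.2 against 5.60, limma adjusted p = 0.0417; 0.0558 to 0.213 without any of 5 libraries), and lenses had been dissected away from the retina. The 10 markers other than those that showed the pattern all lay above LeCre, with a median log2 difference of 0.324 (bootstrap SD 0.098), or 0.293 (bootstrap SD 0.154) in the 6 that no fixed list held, under the 0.5 taken as the least that tissue carried into the pools would give. That bound was a poor one, a condition added after the result: the 10 markers lie near the floor (0.933 to 6.67 FPKM in LeCre, median 2.75), where the added 1 shrinks differences, so carried tissue and a change in the lens itself cannot be told apart. A lower share of lens cells would raise all other cell types alike. Endothelial markers (mean -0.10, 9 genes) and mesenchyme and pigment markers (mean 0.785, 10 genes) moved apart (two-sided exact permutation p = 0.00455 across genes). The changes of these lists had been seen before the test was chosen, and genes measured in the same pools are not independent. The mesenchyme list call was also lost without Fgfr2 pool 2 (camera adjusted p = 0.274). This test thus does not decide whether the lens share was lower. Expression of Rbp3 and Col2a1 by lens cells of the Fgfr2 group stays open and was not tested.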

How the results depend on the processing

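The settings with a Y-linked level or a within-group axis as covariate, and those without certain loci, were chosen after seeing the data. Named genes and lists were recomputed under a TPM scaling, a median-of-ratios scaling, a pseudocount of 0.1, no filter and a replicate block. They were also recomputed without each library in turn, and lists with an estimated correlation and with fry. No called named gene or called list changed direction in these fits. In the other settings their directions were not computed. With fry 2 uncalled lists had the opposite direction to camera, pigment cells in Pten against LeCre (adjusted p 0.973 with camera and 0.986 with fry) and retina and neurons in Fgfr2Pten against LeCre (0.915 and 0.777). Counts of called loci stayed within 1.5 times under a TPM scaling, a median-of-ratios scaling, a pseudocount of 0.1, no filter on low values and a robust variance prior. They also did so without the loci listed at 0, and without the all-or-none loci and those within 10 Mb of Fgfr2 or Pten. With the Y-linked level as covariate, the counts were 581 in Fgfr2 against LeCre, 149 in Pten against LeCre, 244 in Fgfr2Pten against LeCre and 178 in the interaction; the cause was not tested. With the within-group axis as covariate, they were 1940, 795, 1113, 3301 (Fgfr2Pten against Fgfr2), 530 (Fgfr2Pten against Pten) and 1003 (interaction), and more calls follow partly from its construction, since the axis is taken from the residuals. With only the 2 groups fitted, Fgfr2Pten against Pten gave 88, with fewer samples to estimate the spread.

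Leaving out 1 library gave 589 to 1106 loci in Fgfr2 against LeCre, 236 to 459 in Pten against LeCre, 236 to 558 in Fgfr2Pten against LeCre, 1056 to 2161 in Fgfr2Pten against Fgfr2, 90 to 220 in Fgfr2Pten against Pten and 211 to 469 in the interaction, with fewer samples in each fit. Of the named calls, 32 of 47, 27 of 39, 29 of 45, 53 of 77, 9 of 17 and 14 of 25 held in every such fit, in the same order of contrasts. Of the 39 list calls, none held with an estimated correlation; with fry, a test that does not compare a list with other genes, 12 lists lost and 4 gained a call. Under a TPM scaling 9 of 524 named values lost a call and 5 gained one. The share of loci called higher moved from 62.1% to 50.8% in Fgfr2Pten against LeCre and from 55.7% to 43.9% in Fgfr2Pten against Fgfr2, where 1056 higher and 840 lower loci became 824 and 1053.

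Libraries with the same number were not paired by the labels. Their deviations from the group means correlated with r from -0.529 to 0.332 across genes, above 0.1 in 5 of 18 pairs. With the number as a replicate block the counts were 808, 340, 364, 1521, 140 and 271, each within 1.5 times, and 25 named values lost a call while 2 gained one. The depth behind the FPKM values is unknown, so what depth limits could not be separated from the spread between pools.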

Other observations

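Except for Vsx2, Six6 and Fgf15, the values in the next paragraphs are of genes outside the naming rule, chosen after their values were seen. Among these, results without single libraries are given only for Rbp3, Col2a1, Col9a1 and Zic1. Of 15 tested genes of retina and ciliary body, Rbp3 and Col2a1 rose in Fgfr2 against LeCre. Rbp3, the retinoid-binding protein of the retina, stood at 54.1 ± 6.97 FPKM in Fgfr2, 12.7 ± 1.78 in Pten, 17.3 ± 2.60 in the libraries labelled Fgfr2Pten and 17.2 ± 1.88 in LeCre (1.59 ± 0.14 in Fgfr2 against LeCre, limma adjusted p = 1.91e-06). Collagen genes also differed between Fgfr2 and Fgfr2Pten. Col2a1 stood at 18.2 ± 7.99 and 2.27 ± 1.48 FPKM (limma adjusted p = 0.0013), and Col9a1 at 59.3 ± 23.0 and 13.1 ± 3.19 (limma adjusted p = 0.00103). The transcription factor gene Zic1 stood at 32.0 ± 11.1 and 5.53 ± 0.451 FPKM in these groups (limma adjusted p = 0.000925). In this contrast the calls of Rbp3, Col2a1, Col9a1 and Zic1 held without any 1 library. Of the 15 genes, Vsx2 (limma adjusted p = 0.00435), Six6 (0.0354), Fgf15 (0.00252), Sfrp2 (0.0244), Lhx2 (0.00496) and Slc1a3 (0.0411) were also lower in Fgfr2Pten. Sox8, Sox9, Hes5, Stmn2 and Dlk1 were not called in it. Against LeCre, Zic1 (limma adjusted p = 0.118) and Col9a1 (limma adjusted p = 0.0561) were not called in Fgfr2.

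Close to Pten on chromosome 19, Gldc, which encodes the glycine decarboxylase of the glycine cleavage system, stood at 213 ± 16.4 FPKM in Pten and 237 ± 12.3 in Fgfr2Pten, against 98.9 ± 8.98 in Fgfr2 and 103 ± 5.25 in LeCre (1.04 ± 0.09 in Pten against LeCre, limma adjusted p = 2.26e-06). Papss2, a sulfate donor synthase gene next to Pten, stood at 4.70 ± 0.200 FPKM in Fgfr2, 2.07 ± 0.850 in Pten, 3.20 ± 0.346 in Fgfr2Pten and 0.267 ± 0.058 in LeCre.

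Libraries of 1 group also differed along an axis taken from their deviations from the group means. Its scores were lowest in Fgfr2Pten pool 3 (-23.8) and Pten pool 2 (-21.3) and highest in Pten pool 3 (26.3) and Fgfr2Pten pool 2 (16.1).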
